A study of Homo sapiens with 4 samples.

How the data were processed

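Chromatin immunoprecipitation sequencing (ChIP-seq) for histone H3 trimethylated at lysine 27 (H3K27me3), a mark of genes silenced by Polycomb complexes, was carried out on human primary monocytes from peripheral blood of healthy donors. The labels list 4 libraries in 2 groups. In one group the cells were cultured for 24 hours with interferon gamma (IFN-γ), in the other for 24 hours without it, and each group has 2 replicates. The labels do not say whether the replicates came from separate donors.

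One table of the whole series was analysed. Per the submitters' processing notes, the reads were handled with CASAVA 1.7 and Bowtie 1.0.1 on the hg19 build; the notes do not give the role or the settings of each. How the regions were called and merged, and how reads were averaged, scaled and pooled, is not given in the sources used here. Per the file header, the table gives regions by chromosome, start and end, 2 columns of values called A and B (average reads, per the name of the table), whose scale is not given in the sources used here, the deposited ratio of B over A, the deposited log2 of that ratio, and 2 sets of text classes of the ratio. The deposited log2 values equalled the log2 of the deposited ratio to within 1e-08. The names A and B match no label, so they could not be tied to a condition, to a replicate or to a mean of libraries. The 2 columns of values themselves were therefore not used, and only the authors' own comparison columns were. Every direction below is B relative to A and says nothing on the effect of IFN-γ. The ratio has no error, the number of libraries behind it and the read depth of each library are not given in the sources used here, and the depth of each region was not analysed here. No interval, detection floor or significance test between conditions is therefore given.

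Before the data were examined, model-based tests over the 4 libraries, gene set tests on 15 fixed gene lists, levels in untreated cells, correlations of replicates and a comparison of splits of the libraries had been planned. None of these could be run, since no value belongs to a library and, for the gene lists, no region was assigned to a gene. Of the plan kept for a pooled table, fold changes with their rank and no test were used in their place. A ranking of the gene list medians among random lists, also kept for a pooled table, was not run. The rule for named items was applied to regions: the 12 regions with the lowest and the 12 with the highest ratio, outside the Y chromosome. The planned threshold of 1.5-fold was kept, and 5/4-fold and 2-fold and the omission of the sex chromosomes had been chosen then as other settings. The runs of neighbouring changed regions, the widths and the bands were examined only after the table had been seen, and so were the alternatives on centring, overlapping regions, width and gap.

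Coordinates are printed as the table gives them, and widths count both end positions. No region ended past its chromosome's end in hg19, whereas 333 regions would do so in hg38. The gene table at hand has GRCh38.p14 coordinates, and no hg19 gene annotation was used here, so no region was assigned to a gene, exon or intron. Regions were placed in cytogenetic bands by their midpoint, with the hg19 band table of the R package circlize 0.4.16. Lengths of hg38 chromosomes came from GenomeInfoDb 1.38.1. The bands of genes are textbook knowledge and were not looked up in a file; a band also holds many other genes, and a region in a gene's band need not belong to that gene. They are given for MERTK, PPARG and TNFRSF11A, for the HOX clusters, and for 41 genes of the fixed list of IFN-γ induced genes. MERTK, PPARG and TNFRSF11A were fixed beforehand on the understanding that the study's authors had examined them, which was not checked here.

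A run was defined as at least 3 autosomal regions changed 1.5-fold or more in one direction, each starting at most 50 kb after the end of those before it, with no region changed as much in the other direction between them. Observed runs were set beside 1000 shuffles of the log2 ratios among regions of the same of 6 width classes. The median or maximum of a band was ranked among 10000 random lists of as many autosomal regions. Such lists ignore position, and neighbouring ratios are alike, so they make medians of bands look more extreme than they are; a ranking among all stretches of as many consecutive regions of an autosome was therefore added after the first ranking had been seen, and both are given. Neither takes account of width. The set of IFN-γ gene bands was ranked among 10000 random sets of bands with like numbers of regions. These rankings describe this table and are not tests across replicates. The run finder was tested on simulated data in which all other ratios were held below the 1.5-fold threshold. Of 40 planted runs of 5 regions changed 2-fold among 24780 regions, 40 were recovered, with 0 other runs. Since other runs could not arise in this setting, it checks the code and gives no rate of missed or false runs. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.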

Results

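The deposited table compared H3K27me3 between 2 sets of values, B and A. The libraries of the series came from human monocytes cultured for 24 hours with or without IFN-γ, a cytokine that activates macrophages. A and B could not be tied to a condition or a replicate, so the comparison need not be one of treated with untreated cells. The table held 25339 regions, which together covered 75.4 Mb of hg19. Region width ranged from 500 to 143983 bp, with a median of 1639 bp and quartiles of 855.5 and 3933 bp. There were no replicate values, so no difference below has a replicate check or a p-value, and the depth behind each ratio was not analysed here.

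The ratio of B over A was close to 1 in most listed regions. How the values were scaled is not given in the sources used here, so a shared shift of H3K27me3 over all regions cannot be judged from it. The median ratio of B over A was 1.01, with quartiles of 0.908 and 1.14, and the ratio changed by less than 1.5-fold in 23651 regions, or 93.3%. At least 1.5-fold lower values in B were found in 936 regions (3.69%), and at least 1.5-fold higher values in 752 regions (2.97%). The lower side reached further. In the authors' deposited table, 298 regions carried the class of a 2-fold or larger decrease and 104 that of a 2-fold or larger increase. In the other set of classes of the authors' deposited table, 85 regions carried the class of a 3-fold decrease, with ratios up to 0.334, and 21 that of a 3-fold increase. Lower regions made up 55.5% of those changed 1.5-fold, or 53.0% with the 127 regions of band 15q23 left out, 74.1% of those changed 2-fold and 44.4% of those changed 5/4-fold, so the side with more regions depended on the threshold. Band 15q23 held 90 regions lower and 2 higher by 1.5-fold, and 1 run in it held 66 regions with ratios below 0.5. The 2-fold and 3-fold counts were not recomputed without this band.

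Change was found mainly in narrow regions, and no region of at least 20 kb was changed by 1.5-fold. Among the 7990 regions of 500 bp to under 1 kb, 6.06% were lower and 6.17% higher by 1.5-fold. Among the 6273 regions from 2 kb to under 5 kb, 2.55% were lower and 0.781% higher. Of the 335 regions of at least 20 kb, 0 were lower and 0 were higher. The SD of the log2 ratio across regions fell from 0.41 in the narrowest to 0.12 in the widest class; regions are not replicates.

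**Figure D1:**
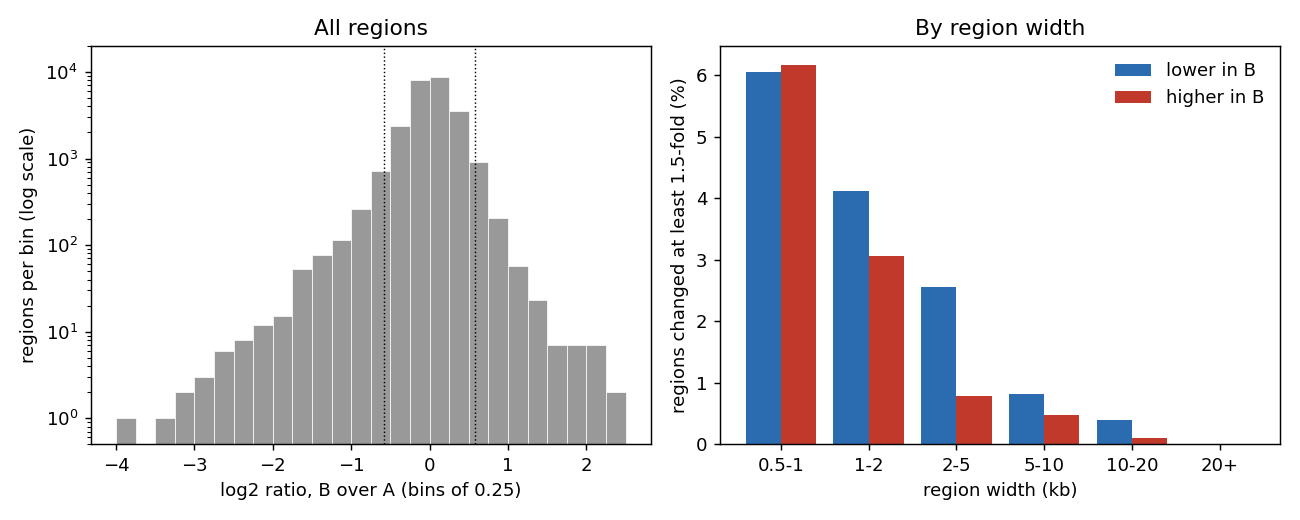
Left, number of regions (log scale) per bin of the log2 ratio of B over A, for all 25339 regions, with dotted lines at 1.5-fold; the lower tail reaches further from 0 than the higher one. Right, percent of regions changed at least 1.5-fold by width class in kb, with lower regions in blue and higher regions in red; both shares are about 6% below 1 kb and 0 from 20 kb.

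The 5 widest regions lay in the bands of the HOX gene clusters, which encode transcription factors of body patterning and are textbook Polycomb targets. A region of 144 kb on chromosome 12 (54316434 to 54460416, band 12q13.13, which holds HOXC) had a ratio of 1.05 in the authors' deposited table. In band 2q31.1, which holds HOXD, a region of 120.6 kb (chromosome 2, 176942939 to 177063528) had a ratio of 1.04 in the authors' deposited table. This region was listed a further time in the authors' deposited table with a start at 176942960 and the same ratio of 1.04. The widest region of 17q21.32, the band of HOXB, spanned 46638853 to 46728015 on chromosome 17 with a ratio of 1.05 in the authors' deposited table. The widest region of 7p15.2, the band of HOXA, spanned 27181446 to 27264030 on chromosome 7 with a ratio of 0.934 in the authors' deposited table. These regions differed by less than 1.1-fold between B and A, whereas narrower regions of 7p15.2 reached 0.219 and 3.99 in the authors' deposited table. The median log2 ratio was 0.16 over the 75 regions of 7p15.2, 0.19 over the 157 of 2q31.1, 0.10 over the 118 of 12q13.13 and 0.09 over the 102 of 17q21.32. These medians exceeded 93.7%, 98.3%, 79.8% and 75.4% of those of stretches of as many consecutive regions, and between 99.5% and 100% of those of random lists that ignore position. The next 5 listed regions by width had ratios below 1 in the authors' deposited table. They were a region of 75.2 kb in 8q24.3 (chromosome 8, 142020731 to 142095934), listed 3 times in the authors' deposited table with ratios of 0.845 to 0.846, one of 62.2 kb in 1q32.1 (chromosome 1, 202579444 to 202641682) with a ratio of 0.864, and one of 62.8 kb in 13q32.3 with a ratio of 0.997 in the authors' deposited table.

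The lowest ratios were concentrated in band 16p13.13. This band holds SOCS1, a feedback inhibitor of cytokine signalling, and CIITA, the main activator of MHC class II genes, both on the list of IFN-γ induced genes. The 4 lowest ratios of the authors' deposited table all lay there, on chromosome 16: 0.066 at 11326847 to 11327443, 0.0932 at 11420867 to 11422018, 0.107 at 11390897 to 11392026 and 0.122 at 11418996 to 11419700. The first corresponds to a 15.1-fold lower value in B. Of the 24 regions of the band, 6 were lower by 1.5-fold or more and 0 were higher, and the median log2 ratio of the band was -0.09, so that the change was local within it.

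The other 8 regions of the lowest 12 were spread over 8 bands, with ratios from 0.13 to 0.169 in the authors' deposited table. They lay in 6q24.2, 15q23, 1q32.3, 2p25.2, 20q13.12, 17q25.3, 16q24.3 and 11q23.2. The region in 17q25.3, the band that holds SOCS3, a further inhibitor of cytokine signalling, spanned 76353261 to 76355790 on chromosome 17 and had a ratio of 0.162 in the authors' deposited table.

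Of the 31 bands of IFN-γ induced genes, 7 held a region lower and 7 a region higher by 2-fold or more, a listing chosen after the values had been seen. Besides 16p13.13 and 17q25.3, the lowest ratios of the authors' deposited table were 0.187 in 6p21.31 (ETV7), 0.201 in 4p15.32 (CD38 and LAP3), 0.235 in 11p15.5 (IRF7), 0.353 in 11q13.1 (BATF2) and 0.465 in 11q22.3 (CASP1). The highest ratios of the authors' deposited table were 4.58 in 1p22.2 (GBP1, GBP2, GBP4 and GBP5), 3.51 in 10q23.31 (ANKRD22), 3.26 in 6p21.31 (ETV7), 2.42 in 6p21.32 (HLA-DRA, TAP1 and PSMB9), 2.22 in 5q31.1 (IRF1), 2.06 in 4q21.1 (CXCL9, CXCL10 and CXCL11) and 2.05 in 3q25.1 (P2RY14). Each value is the extreme over all regions of its band, which numbered 6 in 4p15.32 and 145 in 5q31.1. The region behind it need not belong to the genes named. Random sets of bands with like numbers of regions held a median of 7 bands with such a lower and 4 with such a higher region.

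The highest ratios came from 12 regions in 12 bands on 9 chromosomes. The highest ratio of the authors' deposited table was 5.63, at 76423754 to 76425055 on chromosome 12 (12q21.2). It was followed in the authors' deposited table by 5.36 at 11427457 to 11433532 on chromosome 4 (4p15.33) and 4.69 at 38545065 to 38545884 on chromosome 15 (15q14). A region in 1p22.2, the band of the guanylate-binding protein genes GBP1, GBP2, GBP4 and GBP5, had a ratio of 4.58 in the authors' deposited table (chromosome 1, 89890784 to 89891305). The bands 2q36.3 (4.55), 13q14.13 (4.51), 8p21.3 (4.14), 7p15.1 (4.01), 7p15.2 (3.99) and 4p14 (3.69) each held 1 further region, with the ratio of the authors' deposited table in parentheses. A ratio of 3.51 in the authors' deposited table was found in 10q23.31 (chromosome 10, 90698966 to 90699645), where all 3 regions of a 4.89 kb stretch were higher.

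The bands of MERTK, PPARG and TNFRSF11A each held regions with ratios above 1 and regions with ratios below 1. The highest ratio lay further from 1 than the lowest in each. MERTK is a receptor for the clearance of apoptotic cells, PPARG a nuclear receptor of lipid metabolism and TNFRSF11A the receptor RANK of osteoclast formation. In 2q13, the band of MERTK, a region at 112654378 to 112658842 on chromosome 2 had a ratio of 4.47 in the authors' deposited table, the 7th highest of the autosomes. In 18q21.33, the band of TNFRSF11A, a region at 59990384 to 59998105 on chromosome 18 had a ratio of 2.57 in the authors' deposited table (32nd highest). In 3p25.2, the band of PPARG, a region at 12327409 to 12330753 on chromosome 3 had a ratio of 2.42 in the authors' deposited table (40th highest). The lowest ratios of the authors' deposited table were 0.664 in 2q13, 0.501 in 18q21.33 and 0.601 in 3p25.2. At 1.5-fold, 3 regions were higher and 1 lower in 2q13, 4 were higher and 2 lower in 18q21.33, and 3 were higher and 2 lower in 3p25.2. The maximum exceeded that of 98.7% of stretches of as many consecutive regions for 2q13, 96.0% for 18q21.33 and 93.7% for 3p25.2, and that of 98.9%, 96.0% and 93.0% of random lists. The medians were less extreme once neighbours were kept together. The median log2 ratio over the 43 regions of 2q13 was -0.08, above 17.7% of the medians of stretches and 1.43% of those of random lists, opposite in direction to its highest region. It was 0.12 over the 33 regions of 18q21.33 (above 80.6% of stretches and 97.4% of random lists) and 0.03 over the 43 of 3p25.2 (48.4% and 57.9%).

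Changed regions were grouped along the chromosomes far more than shuffled ratios were. On the autosomes, 57 runs of lower regions held 369 of the 928 lower regions (39.8%), against a median of 24 regions and at most 53 in 1000 shuffles among regions of like width. The 26 runs of higher regions held 102 of the 725 higher regions (14.1%), against a median of 12 and at most 37 in the shuffles.

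The longest run lay in 15q23, where 76 consecutive regions from 70274383 to 70812237 on chromosome 15 (538 kb) were all lower in B. Their median ratio was 0.367 with quartiles of 0.313 and 0.441, and the longest lower run of any shuffle had 8 regions. Another run of 11 lower among 12 regions lay at 69869554 to 69979526, with a median ratio of 0.483. The 3 regions between the runs had a median log2 ratio of -1.18. The next 10 regions above the longer run had a median log2 ratio of -0.06, and 0 of them were lower by 1.5-fold. Over all 127 regions of 15q23 the median log2 ratio was -1.16, the lowest of the 561 autosomal bands with at least 10 regions.

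Outside 15q23, 6 runs held at least 10 lower regions. In 8q12.2, 14 of 14 regions over 96.0 kb were lower, with a median ratio of 0.472. Lower regions made up 13 of 15 in 10q11.22 (75.2 kb, median ratio 0.407) and 11 of 12 in 10q22.1 (77.6 kb, median ratio 0.497). The other runs were more mixed and shallower, with 13 of 19 regions lower in 8q24.3 (100.1 kb, median ratio 0.637), 11 of 17 in 16q24.3 (95.1 kb, median ratio 0.597) and 10 of 14 in 4p16.1 (111 kb, median ratio 0.560). A run of 5 regions in 11q23.2 (14.9 kb), chosen for mention after its values had been seen, had a median ratio of 0.197.

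The longest run of higher regions lay in 9p21.3, the band that holds the type I interferon gene cluster and the cell cycle inhibitor genes CDKN2A and CDKN2B; these genes were chosen for mention after the values had been seen. From 21350250 to 21453413 on chromosome 9, 16 of 23 regions were higher by 1.5-fold, with a median ratio of 1.80. A further run at 21236577 to 21257814 had 5 of 6 regions higher, with a median ratio of 1.73. The weakest of the 3 runs of the band, at 22062226 to 22148695, had 4 of 17 regions higher and a median ratio of 1.30. Of all 82 regions of 9p21.3, 27 were higher by 1.5-fold and 0 lower, and the median log2 ratio was 0.38.

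**Figure D2:**
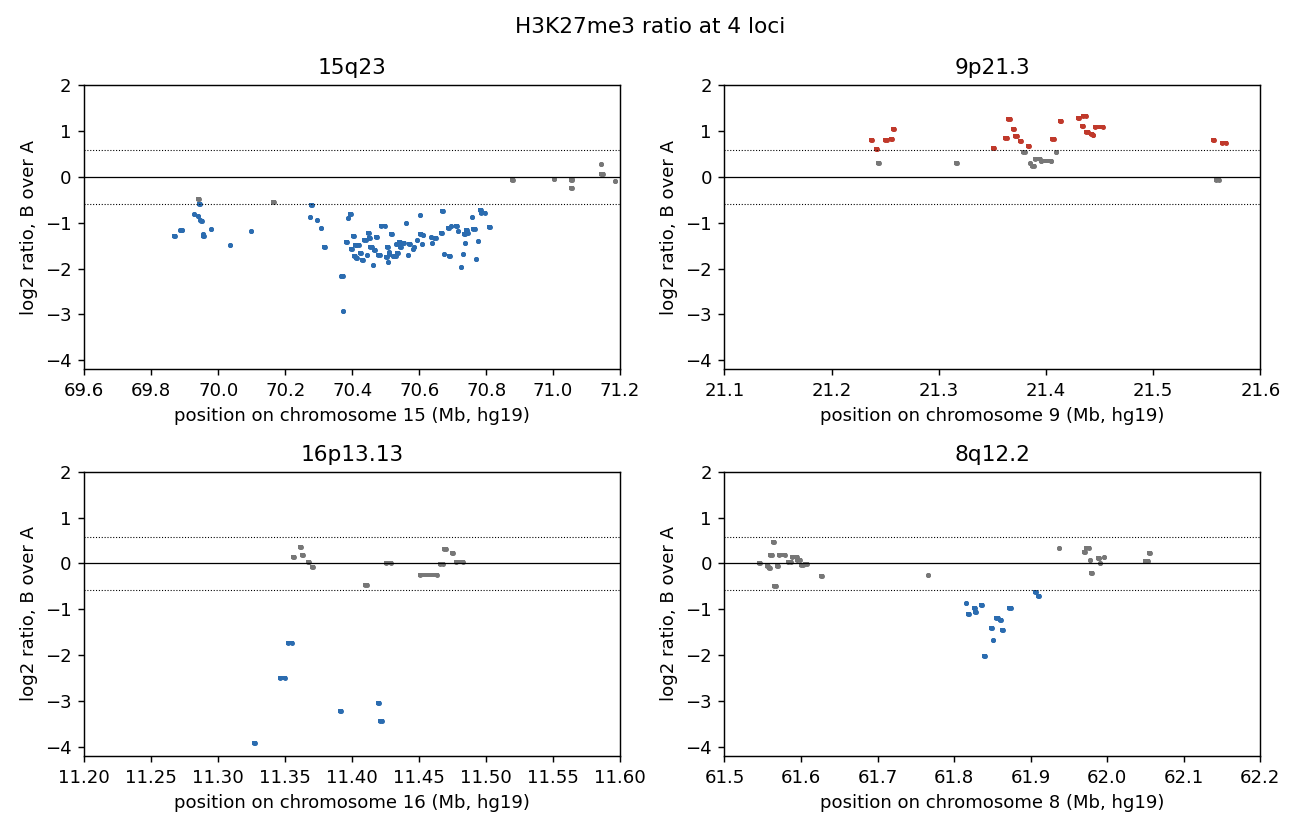
Log2 ratio of B over A (vertical axis) for each region, drawn as a bar from its start to its end along the chromosome (horizontal axis, Mb, hg19), in 15q23, 9p21.3, 16p13.13 and 8q12.2. Blue marks regions lower and red regions higher by at least 1.5-fold (dotted lines), grey the others; the 76 regions of the 15q23 run all lie below the lower line, whereas in 16p13.13 a few deep regions stand among regions near 0.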

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

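No paired analysis was possible because no value of the table belongs to a library or carries a replicate number; for the same reason no library could be left out, and the settings chosen beforehand for the pseudocount, the filter on low values, the scaling of each library, quantile normalization, limma's trend, camera and the choice of row per gene were not run. Of 61 alternative values 38 stayed close to the reported one, that is, within 1.5 times a reported count, within 1.5 times the distance of a reported percentile from the nearer end of the scale, or within the 95% Wilson interval of the reported share (53.1% to 57.8%), an interval that is too narrow because neighbouring regions are not independent. This tally does not measure robustness. Leaving out few regions can hardly move a count, whereas another threshold readily does. For the medians of 7p15.2 and 2q31.1 the reported percentile was 100, and no value could then count as close. The threshold turned the balance: at 5/4-fold, 2616 regions were lower and 3278 higher (44.4% lower, so higher regions prevailed), and at 2-fold, 298 were lower and 104 higher (74.1% lower). Leaving out regions under 1 kb left 452 lower and 259 higher (63.6% lower). Centring the log2 ratios on their median, a shift of 0.02, gave 59.8% lower with 1003 lower and 674 higher regions, and 19 higher runs with 74 regions in place of 26 with 102. Leaving out band 15q23 left 846 lower and 750 higher (53.0% lower). With the X and Y chromosomes left out, 928 were lower and 725 higher. Reducing overlapping regions to the widest of each group removed 863 regions and gave 922 and 749. For the runs, a 2-fold threshold left 21 lower and 2 higher runs with 154 and 10 regions, the longest higher run then having 7 regions; the longest lower run, in 15q23, had between 66 and 76 regions over the alternatives run. Gaps of 25 kb and 100 kb gave 52 and 63 lower runs, and 20 and 31 higher runs. Ranked among stretches of consecutive regions in place of random lists, an alternative added after the first ranking had been seen, the 3 maxima stayed close, but none of the 7 band medians did: that of 2q13 went from 1.43% to 17.7%, that of 18q21.33 from 97.4% to 80.6%, and that of 3p25.2 crossed the middle, from 57.9% to 48.4%; those of the HOX bands fell to between 75.4% and 98.3%. Read depth was not analysed here, so how far it limits the ratios of narrow regions is not stated.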

Other observations

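All tests in this part were chosen after the table had been seen. The ratio of B over A also differed slightly with chromosome banding, and a technical difference between A and B was not told apart from one in the mark. The median log2 ratio was 0.10 over the 1084 regions in the darkest bands (gpos100), 0.09 over the 1657 regions in gpos75 and 0.08 over the 3265 in gpos50 bands. It was -0.01 over the 3023 regions in gpos25 bands and -0.00368 over the 15609 in unstained (gneg) bands. Among regions of at least 5 kb the same contrast was 0.05 in gpos100 and -0.02 in gneg bands. By autosome, the median ranged from -0.08 on chromosome 19 and -0.06 on chromosome 22 to 0.09 on chromosome 6. Opposite differences lay side by side in 20q13.12, where a region at 44747320 to 44748171 on chromosome 20 had a ratio of 0.16 in the authors' deposited table, and a run of 3 higher regions from 44750554 to 44758018 had a median ratio of 1.84. Bands with a raised median included 7p21.2 (0.41 over 20 regions) and 4q21.23 (0.34 over 23 regions), and bands with a lowered median, after 15q23, 14q31.1 (-0.36 over 17 regions).

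Runs of changed regions, lower and higher, are the pattern a reader may want to follow up. Noise that is independent between neighbours, and of like size in regions of like width, would leave about as many regions in runs as shuffling does. Here, 369 lower and 102 higher regions were in runs, above the highest shuffled values of 53 and 37. Regions listed more than once do not account for it either, since with overlapping regions reduced to the widest 357 lower and 99 higher regions were in runs, above the highest values of 56 and 34 in 1000 shuffles of the reduced list. Noise shared by neighbours, independent noise that is larger in some stretches than in others, and a real regional change stay open. The shuffles took account of width only, so they cannot tell these apart. An effect of IFN-γ on the runs was not tested, because A and B could not be tied to a condition.

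For the 2 runs of lower regions in 15q23, a candidate explanation is the loss of 1 of 2 copies of the segment in the material behind B. That would put the ratios around 0.5. In the run of 76 regions the upper quartile was 0.441, and 66 of the 76 ratios were below 0.5, so most lay under that value. In the neighbouring run of 11 lower regions the quartiles were 0.440 and 0.554, which include 0.5. Only regions at least 1.5-fold lower count towards a run, so ratios near 0.5 are no evidence of a loss. The 3 regions between the runs had a median log2 ratio of -1.18, and the split between the runs comes from the definition of a run. Quartiles describe the spread across regions and are no error of the ratio of the segment. Noise shared by neighbours could move that ratio as a whole. The quartiles also include 0.5 in runs on other chromosomes. They therefore speak neither for nor against a loss, which stays open for both runs. A change of the mark over the segment, and losses in both copies of part of the cells, stay open for both and were not tested.

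Changed regions were mostly narrow, which may come from fewer reads in narrow regions. The SD of the log2 ratio across regions was 0.41 under 1 kb and 0.12 from 20 kb. Values per region were not used here, so noise and a real excess of change in narrow regions were not told apart.

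One hypothesis was that the bands of IFN-γ induced genes more often hold strongly changed regions than other bands. Of the 31 bands of the 41 genes, 7 held a region lower by 2-fold or more, and 66.7% of 10000 random sets of bands with like numbers of regions held at least as many (median 7). A region higher by 2-fold or more was held by 7 of the 31 bands, and 8.39% of the random sets held at least as many (median 4). In neither direction could these bands be told from random ones. A band spans many genes, so this coarse test does not bear on single genes such as SOCS1 or CD38.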
